A study of Mus musculus with 3 samples.

How the data were processed

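Single-cell RNA-seq was carried out on mammary epithelial cells of mice in 3 libraries, which the labels place in 1 group with no treatment. Per the labels, the number 4 glands of 4 female FVB/NJ mice aged 10 weeks were pooled, digested with collagenase and trypsin, stained with antibodies to CD49f, EpCAM, CD31, CD45 and Ter119 and with the dead-cell dye SytoxBlue, and live epithelial cells were sorted by flow cytometry. The same text stands for every library, so whether the libraries came from 1 pool of mice or from separate pools is not given in the sources used here. The p-values therefore measure only the spread between these libraries, which may be technical. Libraries were made with the droplet-based 10x Genomics 3' v2 chemistry, in which each captured transcript molecule carries a unique molecular identifier (UMI) and each droplet a barcode.

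The authors deposited 1 table per library of raw UMI counts, with gene symbols and cell barcodes and no normalization. Cell Ranger 2.1.0 and the genome build mm10 are named in the submitters' processing notes. The gene annotation, the rule that separated cells from empty droplets, any filter on genes and any downsampling of reads between libraries are not given in the sources used here. The tables hold 19050 gene symbols, of which 13 are mitochondrial, and 26845 barcodes. Total UMIs were 18584156 in library 1, 27220670 in library 2 and 30984706 in library 3. All 3 tables hold whole numbers, and 0 columns of samples were left unused.

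Barcodes with at least 500 detected genes and under 10% mitochondrial UMIs were kept, which left 26320. Doublets (2 cells in 1 droplet) were scored with Scrublet as implemented in scanpy 1.11.5, library by library, and the highest-scoring cells were removed at a rate of 0.8% per 1000 barcodes. This removed 340, 646 and 982 cells and left 6003, 8288 and 10061. Counts were scaled to 10000 per cell and log-transformed, the 2000 most variable genes and 30 principal components were taken, and cells were clustered with the Leiden method (igraph 0.11.9) at resolution 0.5 on a graph of 20 neighbours. Clusters were named from 79 marker genes of epithelial and other cell types, of which 77 are in the tables. A marker counted for a cluster when it was detected in at least 5% of its cells and at no less than 0.5 of the share of the highest cluster, and a name needed at least 3 markers and no less than 0.5 of those measured. Names end in "-like" because no annotation of cells by the authors was used.

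Cells are not replicates, so raw counts were summed per library and class, which gave 9 sums of at least 20 cells each. To keep a gene from being tested between classes that it helped to define, genes were divided into 2 sets by a hash of the symbol; cells were clustered on each set, genes of the other set were tested, and the p-values of both sets were adjusted together. Of all kept cells, 99.9% received the same class from both sets. The naming markers were not tested. Sums were compared with edgeR 4.0.16 (R 4.3.3), quasi-likelihood test, two-sided, with TMM factors from 1 common reference sum, the filterByExpr filter and the library as a block. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. Levels are TMM-normalised CPM (counts scaled to a common library total), given as mean ± SD over 3 libraries; levels of naming markers and of single libraries are scaled by total counts alone. Fold changes are the fitted values, with the SD of the 3 within-library log2 ratios, and adjusted p-values of single genes are from edgeR. These ratios use log2 CPM with a prior count of 2, so the SD can be narrowed where counts are near 0. A library had a count of 0 in hormone-responsive-like cells for 3 of 46 named entries against basal-like and 5 of 39 against luminal progenitor-like cells. Gene lists were compared with camera in limma 3.58.1 with its preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, two-sided and adjusted over all lists and the 3 comparisons; fry was run beside it. Of 27 lists written, 26 had the 4 measured members needed; the list of keratins of basal and stratified layers did not. Of 598 genes in the lists, 587 are in the tables.

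The library pairs the sums by construction, since the classes of 1 library come from the same suspension. As a check, deviations of the 2 classes from their means were correlated across genes, which are not independent replicates. Correlations within a library lay between 0.19 and 0.415, and those between different libraries at most at 0.0852. Deviations of a class over the 3 libraries sum to 0 for each gene, which lowers the values between libraries. Those values are therefore no separate support for the pairing. The cell filters, clustering settings, markers, gene lists, tests and the rule for named genes were fixed before the data were examined; the detection shares behind a cluster's name and the common TMM reference were set afterwards. Named genes are, per comparison and direction, the 6 called genes with the largest absolute log2 fold change that kept their sign in all 3 libraries, reached a mean of 50 CPM in the higher class, and were neither naming markers nor predicted genes; and, from each list with an adjusted p below 0.05, up to 2 called members per direction with the smallest p. Gene positions are from the GENCODE release M21 annotation of GRCm38, the assembly that mm10 denotes.

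The test was tried on simulated data. Counts for the real genes were drawn with the totals of the real sums and the spread of their fitted trend. The 3 classes of a library shared the same mean proportions, so no class difference was present before genes were changed. Then 200 genes were changed by known amounts, and 30 list genes by a log2 fold of 0.8. For basal against luminal progenitor, 40.3%, 93.9% and 98.4% of genes changed by a log2 fold of 1, 2 and 3 were called, among 12859 genes. For basal against hormone-responsive luminal, these shares were 46.2%, 96.9% and 100% among 12812 genes, and for luminal progenitor against hormone-responsive luminal 39.4%, 96.8% and 98.5% among 12838 genes. Of the unchanged genes, 3, 3 and 2 were called in the 3 comparisons. The real sums hold many class differences at once, which the simulation lacks, so these shares and counts may not carry over to them.

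Shares of cells have exact Clopper-Pearson intervals at the 95% level, and where no cell was found, the limit is the share that 3 cells would make; both cover counting error only. Shares of cells with a UMI of a gene were also computed after thinning each cell at random to 2000 UMIs (cell-cycle genes) or 1000 UMIs (other genes), leaving out shallower cells. Alternatives were median-of-ratios size factors, no low-count filter, DESeq2 1.42.0, no replicate block, only the 6 sums of the 2 classes compared, looser (200 genes, 20%) and stricter (1000 genes, 5%) cell filters, no doublet removal and Scrublet's automatic threshold, resolutions of 0.3 and 1, each library clustered on its own, classes from all variable genes, sums thinned to equal totals, an estimated inter-gene correlation for the lists, and each library left out in turn. edgeR's default, a TMM reference chosen separately in each set, was added as an alternative after seeing the data. Scripts were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.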

Results

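Sorted mammary epithelial cells of 10-week-old female FVB/NJ mice were profiled by droplet single-cell RNA-seq in 3 libraries of 1 untreated group. The libraries held 6691, 9034 and 11120 barcodes, with a median of 2333, 2525 and 2335 UMIs and 1138, 1266.5 and 1161 detected genes per barcode. The median share of mitochondrial UMIs was 2.84%, 1.79% and 1.88%. After filtering, 24352 cells remained. Counts differed between every pair of libraries by more than sampling noise within each main class (chi-square per degree of freedom 5.79 to 98.5), which excludes only that 1 library is present under 2 names. The libraries were taken as 3 replicates, although the labels do not say whether they share a pool of mice. The labels give no contrast between libraries, and the comparisons below are between cell classes within the same libraries.

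Cells formed 13 clusters, which fell into 3 epithelial classes and a small non-epithelial remainder. Basal-like cells (10377) carried the myoepithelial keratin Krt14 at 2543 ± 221 CPM and the smooth-muscle actin Acta2 at 6364 ± 1412 CPM (mean ± SD, n = 3). Luminal progenitor-like cells (10782) carried Elf5, a regulator of the secretory lineage, at 504 ± 19.7 CPM, the receptor Kit at 260 ± 41.7 CPM and kappa-casein (Csn3) at 4238 ± 1212 CPM. Hormone-responsive luminal-like cells (2901) carried the prolactin receptor Prlr at 3028 ± 109 CPM, the progesterone receptor Pgr at 280 ± 87.9 CPM, the oestrogen receptor Esr1 at 132 ± 12.7 CPM and the growth factor Areg at 1364 ± 424 CPM. These genes named the classes and are not results of a comparison. Krt14 UMIs were present in 88.9% of basal-like cells and in 24.3% of luminal progenitor-like cells, at median depths of 1923 and 2930 UMIs per cell; Acta2 UMIs were present in 95%, 31.6% and 31.3% of basal-like, luminal progenitor-like and hormone-responsive-like cells. Hormone-responsive-like cells had a median depth of 3390 UMIs. The luminal shares of both genes are not read as expression, and their source was not tested. They differed between libraries: Acta2 UMIs were present in 13.4%, 47.7% and 33.8% of luminal progenitor-like cells of libraries 1, 2 and 3.

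Basal-like cells made up 29.7% (95% interval 28.6 to 30.9) of library 1, 53.7% (52.6 to 54.8) of library 2 and 41.2% (40.2 to 42.2) of library 3, a mean of 41.5% ± 12.0. Luminal progenitor-like cells made up 63.2% (61.9 to 64.4), 31.8% (30.8 to 32.8) and 43.3% (42.3 to 44.3), a mean of 46.1% ± 15.9. Hormone-responsive-like cells made up 6.60% (5.98 to 7.25), 13.0% (12.3 to 13.8) and 14.2% (13.5 to 14.9), a mean of 11.3% ± 4.08. The libraries differed by far more than counting error, and basal-like and luminal progenitor-like cells changed order between them, so no order of these 2 classes is read from the means. The sort on CD49f and EpCAM can set these shares. Within classes, different clusters held the cells of different libraries: 90.5% of cluster 2 (luminal progenitor-like), 98.6% of cluster 7 (basal-like) and 93.1% of cluster 11 (hormone-responsive-like) came from library 1, and 91.9% of cluster 9 (luminal progenitor-like) from library 2. Immune or stress genes were among the genes that lead some named clusters, namely Tnf and Cxcl2 in cluster 1, Hsph1 and Slpi in cluster 7, Saa1 in cluster 8 and Ccl20 in cluster 9. Cluster 8 (luminal progenitor-like) was also led by milk genes, among them Csn1s2a, Csn2 and Wap, and cluster 9 by the S-phase gene Uhrf1. The casein-rich cluster 8 held 0.237%, 18.4% and 20.3% of luminal progenitor-like cells of libraries 1, 2 and 3.

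**Figure D1:**
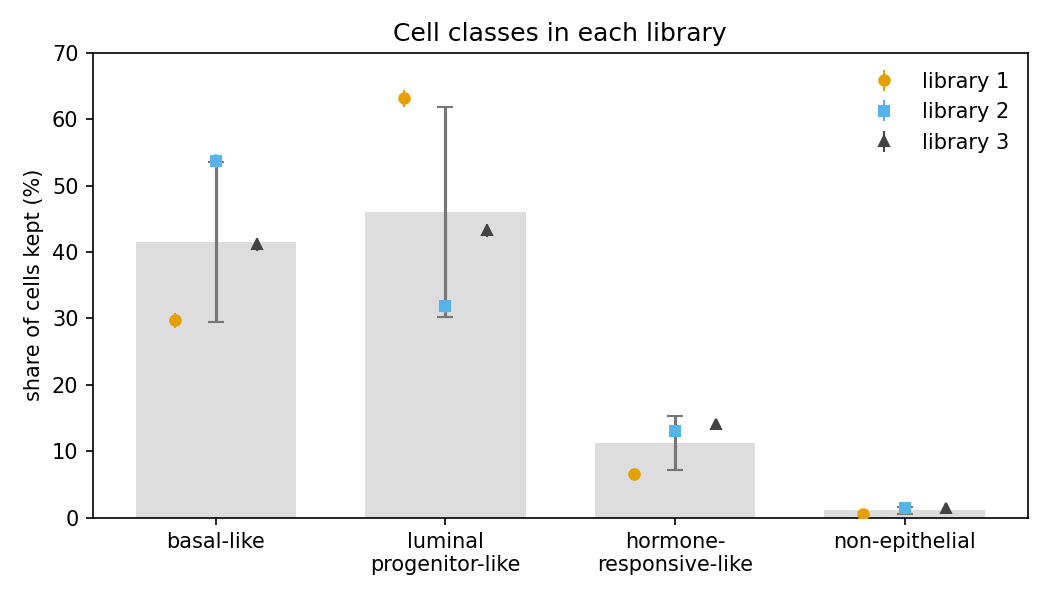
Share of kept cells (%, vertical axis) in each class; points are the 3 libraries with exact 95% intervals, grey bars the mean and grey lines the SD over libraries. Library 1 had the highest share of luminal progenitor-like cells (63.2%) and the lowest shares of basal-like (29.7%) and hormone-responsive-like cells (6.60%).

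Non-epithelial clusters held 0.533%, 1.46% and 1.38% of cells. Of these, cluster 13 was fibroblast-like (138 cells), led by the collagen genes Col1a1 and Col3a1, and cluster 12 carried both endothelial and pericyte markers (154 cells). Counted cell by cell on at least 3 markers, fibroblast-like cells numbered 6, 76 and 92, endothelial-like cells 20, 31 and 29, pericyte-like cells 6, 20 and 20, and immune-like cells 1, 6 and 9 in the 3 libraries. The sort used antibodies to CD31, CD45 and Ter119, which mark endothelial, immune and red blood cells, and would remove most of those types. Erythroid-like cells numbered 1, 8 and 6, Schwann-like cells 0, 1 and 1, and skin keratinocyte-like cells 0, 0 and 2. Of these, only 0, 0 and 3 erythroid-like and 0 keratinocyte-like cells lay in non-epithelial clusters, and the erythroid markers Hba-a1, Hba-a2 and Alas2 had UMIs in 20.7%, 6.23% and 1.80% of hormone-responsive-like cells, against 0.605%, 0.106% and 0.0155% of basal-like cells, at median depths of 3390 and 1923 UMIs. Adipocyte-like and skeletal muscle-like cells numbered 0 in each library, which allows shares of up to 0.05%, 0.0362% and 0.0298%.

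The share of cells with a UMI of Top2a or Mki67, genes of dividing cells, was 2.75% ± 1.48 in basal-like, 4.89% ± 2.62 in luminal progenitor-like and 1.55% ± 0.711 in hormone-responsive-like cells (n = 3) after thinning to 2000 UMIs. Without thinning the shares were 2.34% ± 0.940, 6.84% ± 4.32 and 2.76% ± 0.660, so the order of basal-like and hormone-responsive-like cells turned without thinning and is not read. Thinning left out 926, 1877 and 2816 basal-like, 1138, 612 and 986 luminal progenitor-like and 97, 227 and 319 hormone-responsive-like cells. In luminal progenitor-like cells the share was 2.00%, 7.11% and 5.55% in libraries 1, 2 and 3. No test of these shares was run.

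Between basal-like and luminal progenitor-like cells, an actin-binding and an adhesion gene were among those higher in basal-like cells, and a casein and a tight-junction gene among those higher in luminal progenitor-like cells. Tagln, a smooth-muscle actin-binding protein (chromosome 9, 45929619 to 45936058, minus strand), reached 1909 ± 672 CPM in basal-like and 23.2 ± 2.06 CPM in luminal progenitor-like cells, a log2 fold change of 6.32 ± 0.48 (adjusted p = 2e-07). Tenm2, a transmembrane adhesion protein (chromosome 11, 36006656 to 37235964, minus strand), reached 216 ± 38.5 and 1.85 ± 0.253 CPM, a log2 fold change of 6.85 ± 0.40 (adjusted p = 1.8e-07). In the other direction, beta-casein Csn2 (chromosome 5, 87692624 to 87699630, minus strand) reached 106 ± 92.1 CPM in basal-like and 4431 ± 3963 CPM in luminal progenitor-like cells, a log2 fold change of -5.34 ± 0.21 (adjusted p = 2e-07). The tight-junction protein Cldn7 (chromosome 11, 69964779 to 69967885, plus strand) reached 15.2 ± 0.635 and 298 ± 3.77 CPM, a log2 fold change of -4.29 ± 0.06 (adjusted p = 1.8e-07). All genes given here with a value kept 1 sign in all 3 libraries.

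Of 12843 genes tested, 4021 were called between basal-like and luminal progenitor-like cells, 2417 higher in basal-like and 1604 higher in luminal progenitor-like cells, and 3985 of them kept 1 sign in all 3 libraries. An unadjusted p below 0.05 was reached by 7674 genes. The 6 largest differences towards basal-like cells were in Speer4e (log2 fold change 7.18 ± 0.75), Tenm2, the protocadherin Pcdh7 (6.49 ± 0.86), the G1 cyclin Ccnd2 (6.46 ± 0.44), the non-coding RNA Meg3 (6.36 ± 1.54) and Tagln. Speer4e belongs to a family of near-identical copies and its counts are uncertain. Towards luminal progenitor-like cells they were in Lao1, an amino-acid oxidase found in milk (-5.37 ± 0.39), Csn2, the lipogenic regulator Thrsp (-5.31 ± 0.25), the alpha-S2 casein Csn1s2a (-5.26 ± 0.48), carbonic anhydrase Car2 (-5.26 ± 0.12) and the alpha-S1 casein Csn1s1 (-5.26 ± 0.04). Casein UMIs in basal-like cells followed those of the luminal progenitor-like cells of the same library: Csn2 stood at 4.26, 169 and 116 CPM in basal-like and at 156, 8159 and 4863 CPM in luminal progenitor-like cells of libraries 1, 2 and 3.

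**Figure D2:**
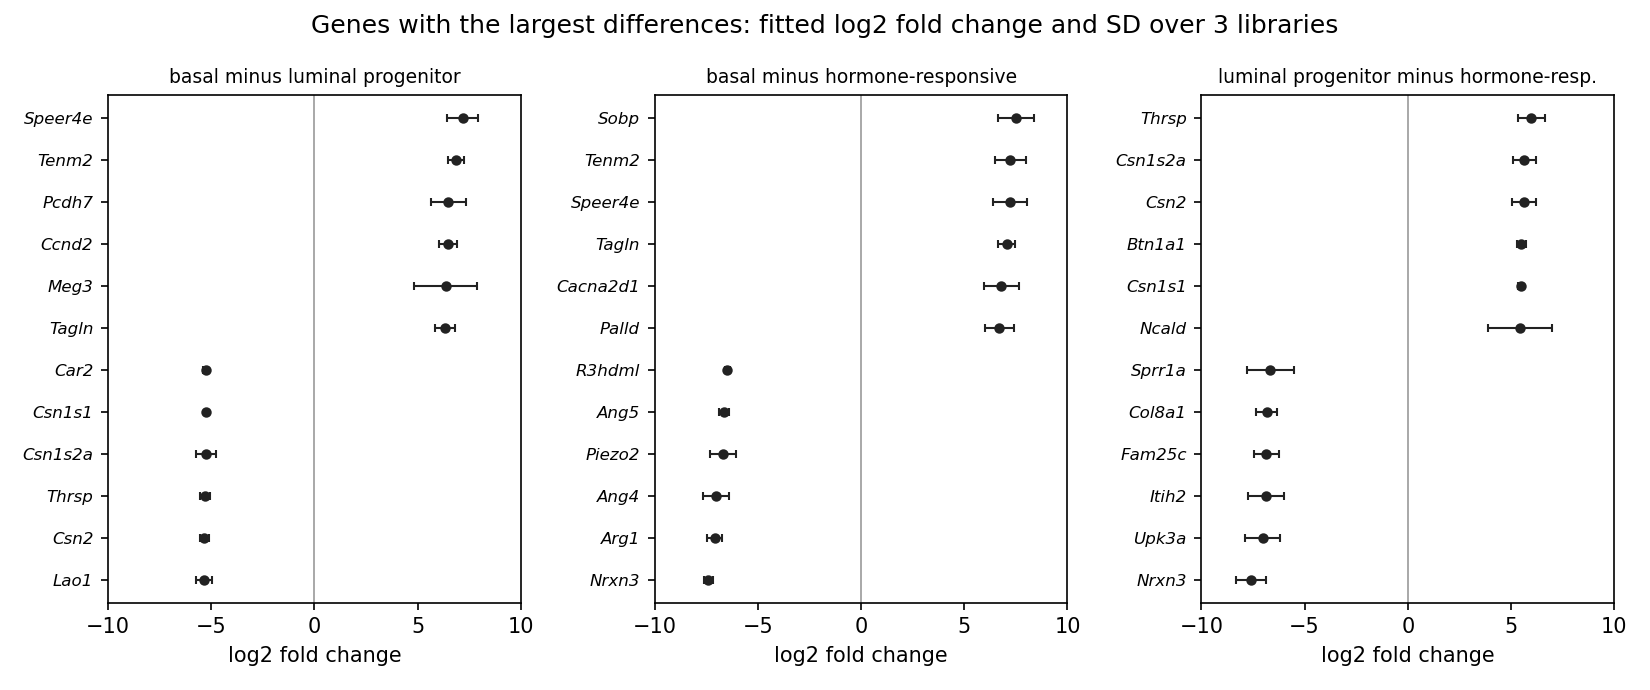
Fitted log2 fold change (horizontal axis) of the 6 genes with the largest differences in each direction for the 3 comparisons; points are fitted values and bars the SD of the within-library log2 ratios of 3 libraries. Values to the right are higher in the class named first, from Tagln (6.32) to Speer4e (7.18) in the first comparison, and values to the left are higher in the class named second.

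Lists fixed in advance gave the following picture of the same comparison. All 22 measured genes of the contractile apparatus were higher in basal-like cells (22 also when adjusted over the list alone). Contractile genes had a median of 3.85 (adjusted p = 7.9e-14, and adjusted p = 0.076 with an estimated correlation). An example was calponin Cnn2 (3.88 ± 0.16). Of 26 basement membrane and matrix genes, 24 were higher, 0 lower and 2 not called (24 and 0 adjusted over the list alone). Matrix genes had a median of 2.99 (adjusted p = 3e-12, and adjusted p = 0.076 with an estimated correlation). An example was perlecan Hspg2 (2.98 ± 0.10). In basal-like cells of library 1 this list had a median log2 ratio of -0.55 to the other libraries (4 of 25 genes over 2-fold lower, 1 higher). Such ratios use genes of at least 10 CPM. In luminal progenitor-like cells the ratio was -0.47 in library 1 (5 of 21 lower) and 0.44 in library 2 (4 higher). Of 21 integrin and focal adhesion genes, 16 were higher, 1 lower and 4 not called (16 and 1 adjusted over the list alone). Adhesion genes had a median of 1.70 (adjusted p = 5.6e-07, and adjusted p = 0.076 with an estimated correlation). Itga9 (5.26 ± 0.15) and the hemidesmosome linker Dst (3.66 ± 0.13) were higher and Itgb6 (-1.20 ± 0.18) lower, the latter at -0.96 with sums thinned to equal totals (adjusted p = 0.0885, range over 18 alternatives 0.000215 to 0.0885). All 15 epithelial-mesenchymal markers were higher (15 adjusted over the list alone). Mesenchymal markers had a median of 4.15 (adjusted p = 1.1e-07, and adjusted p = 0.076 with an estimated correlation). Examples were the transcriptional repressor Snai2 (5.89 ± 0.44) and the focal adhesion protein Tgfb1i1 (5.17 ± 0.40). Over the 5 markers of at least 10 CPM in luminal progenitor-like cells, the median log2 ratio was 0.57 in library 2.

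Among regulators, 13 of 19 basal transcription factors were higher, 2 lower and 4 not called (13 and 2 adjusted over the list alone). Basal factors had a median of 2.49 (adjusted p = 0.0013, and adjusted p = 0.11 with an estimated correlation). Mef2c (5.49 ± 0.31) was higher, and Tcf7l2 (-1.21 ± 0.14) and the Notch target Hey2 (-2.88 ± 1.5) were lower. Of 29 Wnt pathway genes, 18 were higher, 3 lower and 8 not called (18 and 3 adjusted over the list alone). Wnt genes had a median of 1.67 (adjusted p = 0.00012, and adjusted p = 0.076 with an estimated correlation). Those higher included the secreted inhibitor Wif1 (5.60 ± 0.63) and the ligand Wnt10a (5.47 ± 0.62), while Rspo1, which amplifies Wnt signalling (-4.41 ± 0.22), and Wnt5b (-2.20 ± 0.20) were lower. Of 23 luminal transcription factors, 8 were lower, 4 higher and 11 not called (8 and 4 adjusted over the list alone). Luminal factors had a median of -0.49 (adjusted p = 0.035, and adjusted p = 0.417 with an estimated correlation). The ETS factor Ehf (-4.94 ± 0.32) and Hey1 (-3.63 ± 0.86) were lower and Runx1 (1.68 ± 0.10) and Tbx3 (2.45 ± 0.54) higher in basal-like cells. This list also missed the threshold without library 2 (adjusted p = 0.055) and without library 3 (adjusted p = 0.0559); over its 9 alternatives adjusted p lay between 0.0165 and 0.417.

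Of 13 milk protein genes, 12 were lower in basal-like cells, 0 higher and 1 not called (13 and 0 adjusted over the list alone). Milk genes had a median of -4.76 (adjusted p = 3.2e-10, and adjusted p = 0.076 with an estimated correlation). An example was butyrophilin Btn1a1 (-4.76 ± 0.15). Library 1 had milk genes at a median log2 ratio of -0.74 in basal-like cells (4 of 9 over 2-fold lower, 1 higher) and -1.26 in luminal progenitor-like cells (6 of 12 lower, 1 higher), where libraries 2 and 3 stood at 0.60 and 0.55. Of 21 tight junction and polarity genes, 17 were lower, 0 higher and 4 not called (17 and 0 adjusted over the list alone). Junction genes had a median of -3.54 (adjusted p = 2.6e-11, and adjusted p = 0.111 with an estimated correlation). Examples were Cldn7 and the trafficking GTPase Rab25 (-3.54 ± 0.14). Of 5 keratins of luminal cells, 4 were lower and 1 higher (4 and 1 adjusted over the list alone). Luminal keratins had a median of -2.23 (adjusted p = 0.016, and adjusted p = 0.46 with an estimated correlation). Krt18 (-3.18 ± 0.17) and Krt7 (-2.23 ± 0.15) were lower and Krt23 (2.62 ± 0.71) higher. These keratins stood in luminal progenitor-like cells at a median log2 ratio of -1.11 in library 1 (3 of 5 over 2-fold lower), 0.19 in library 2 and 0.74 in library 3, and in basal-like cells at -0.26, -0.23 and 0.49. Of 20 genes of fatty acid and triglyceride synthesis, 9 were lower, 1 higher and 10 not called (9 and 1 adjusted over the list alone). Lipid genes had a median of -0.67 (adjusted p = 0.0039, and adjusted p = 0.359 with an estimated correlation). The desaturase Scd1 (-3.09 ± 0.21) was lower and the acyltransferase Dgat2 (1.63 ± 0.33) higher. Lipid genes stood at a median log2 ratio of -0.44, 0.36 and 0.12 in luminal progenitor-like cells of libraries 1, 2 and 3 (4 of 17 over 2-fold lower in library 1). In basal-like cells they stood at -0.20, 0.10 and 0.01. Of 21 innate defence genes, 12 were lower, 2 higher and 7 not called (12 and 2 adjusted over the list alone). Defence genes had a median of -1.98 (adjusted p = 0.0026, and adjusted p = 0.436 with an estimated correlation). The mucin Muc15 (-4.49 ± 0.28) and the chemokine Ccl20 (-4.97 ± 1.39) were lower, and the protease inhibitor Slpi (5.0 ± 1.05) and the chemokine Ccl2 (4.01 ± 0.90) higher. By library, the median log2 ratio of the list was 0.70, -0.53 and -0.21 in basal-like cells (5 of 12 genes over 2-fold higher in library 1) and -1.22, 0.17 and 0.71 in luminal progenitor-like cells (9 of 16 lower in library 1, 7 higher in library 3).

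Of 30 S-phase genes, 12 were lower in basal-like cells, 0 higher and 18 not called (12 and 0 adjusted over the list alone). S-phase genes had a median of -0.80 (adjusted p = 0.0084, and adjusted p = 0.549 with an estimated correlation). Examples were the replication helicase subunits Mcm5 (-1.64 ± 0.17) and Mcm2 (-1.51 ± 0.29; adjusted p = 0.0504 without the replicate block, range over 18 alternatives 3.41e-08 to 0.0504). S-phase genes in luminal progenitor-like cells stood at a median log2 ratio of 0.62 in library 2 (4 of 24 over 2-fold higher) and -0.56 in library 3 (2 lower). Of 34 genes of G2 and M phase, 18 were lower, 0 higher and 16 not called (19 and 0 adjusted over the list alone). G2 and M genes had a median of -1.18 (adjusted p = 0.00038, and adjusted p = 0.504 with an estimated correlation). Examples were Cdk1 (-1.37 ± 0.49) and the spindle protein Nusap1 (-1.73 ± 0.50). In luminal progenitor-like cells, the genes of this list stood lower in library 1 than in libraries 2 and 3 (median log2 ratio -1.12). Of 13 genes of MHC class I presentation, 6 were lower, 0 higher and 7 not called (6 and 0 adjusted over the list alone). Class I genes had a median of -0.64 (adjusted p = 0.016, and adjusted p = 0.616 with an estimated correlation). Examples were the peptide transporter Tap2 (-1.24 ± 0.20) and the immunoproteasome subunit Psmb8 (-1.61 ± 0.48). In luminal progenitor-like cells the median log2 ratio of this list was -0.95 in library 1 (6 of 12 genes over 2-fold lower) and 0.86 in library 3 (5 higher). Without library 3 this call was lost (adjusted p = 0.0777; range over 9 alternatives 0.000355 to 0.616).

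Of 25 dissociation stress and immediate-early genes, 9 were higher in basal-like cells, 0 lower and 16 not called (8 and 0 adjusted over the list alone). Stress genes had a median of 0.86 (adjusted p = 0.027, and adjusted p = 0.744 with an estimated correlation). Examples were Myc (2.15 ± 0.33) and the cytokine-signalling inhibitor Socs3 (4.64 ± 0.74). Without library 1 the median was 0.11 (adjusted p = 0.151), and without the replicate block adjusted p was 0.119 (range over 9 alternatives 0.00191 to 0.744). The whole list had a median log2 ratio of -1.14, 0.11 and 0.95 in luminal progenitor-like cells of libraries 1, 2 and 3 (in library 1, 14 of 25 genes over 2-fold lower and 4 higher), against 0.16, -0.20 and 0.18 in basal-like cells. Its 6 heat-shock genes summed to 19397, 4866 and 4620 CPM in basal-like and to 8460, 3997 and 3677 CPM in luminal progenitor-like cells of libraries 1, 2 and 3. Among housekeeping lists, 0 of 32 nuclear genes of oxidative phosphorylation and 0 of 40 ribosomal protein genes were called, also when adjusted over each list alone. Their medians were -0.33 (adjusted p = 0.0031, and adjusted p = 0.57 with an estimated correlation) and -0.17 (adjusted p = 0.012, and adjusted p = 0.744 with an estimated correlation). Both lists were written as checks, yet both passed by camera with the preset correlation. By library, the oxidative phosphorylation list had a median log2 ratio of -0.38, 0.36 and 0.03 in luminal progenitor-like and -0.22, 0.23 and -0.04 in basal-like cells. By fry, which asks whether the genes of a list move on balance one way, adjusted p was 0.0871 for MHC class I presentation, 0.132 for dissociation stress and 0.0969 for ribosomal proteins, and below 0.05 for the other 15 lists that camera passed in this comparison.

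The other 8 lists did not pass by camera in this comparison, with adjusted p between 0.115 and 0.909, and an adjusted p of 0.396 or more with an estimated correlation. By fry, adjusted p was 0.0017 for the Notch, 0.0048 for the hormone target and 0.0076 for the EGF and FGF list. It was 0.338 or more for the others. Members higher and lower in basal-like cells numbered 11 and 4 of 18 EGF and FGF ligands and receptors, 9 and 4 of 24 hormone targets and paracrine signals, 5 and 6 of 16 Notch pathway genes, 3 and 7 of 17 interferon response genes, 2 and 2 of 18 glycolysis genes, 2 and 1 of 22 unfolded protein response genes, 1 and 2 of 20 cholesterol synthesis genes and 0 and 0 of 5 MHC class II genes. Adjusted over the list alone, the numbers were 11 and 5, 9 and 4, 5 and 6, 3 and 8, 2 and 2, 1 and 1, 1 and 2, and 0 and 0. Median, mean and test differed in sign for the Notch list (median -0.36, mean 0.49) and the glycolysis list (median 0.01, mean 0.09, test lower).

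**Figure D3:**
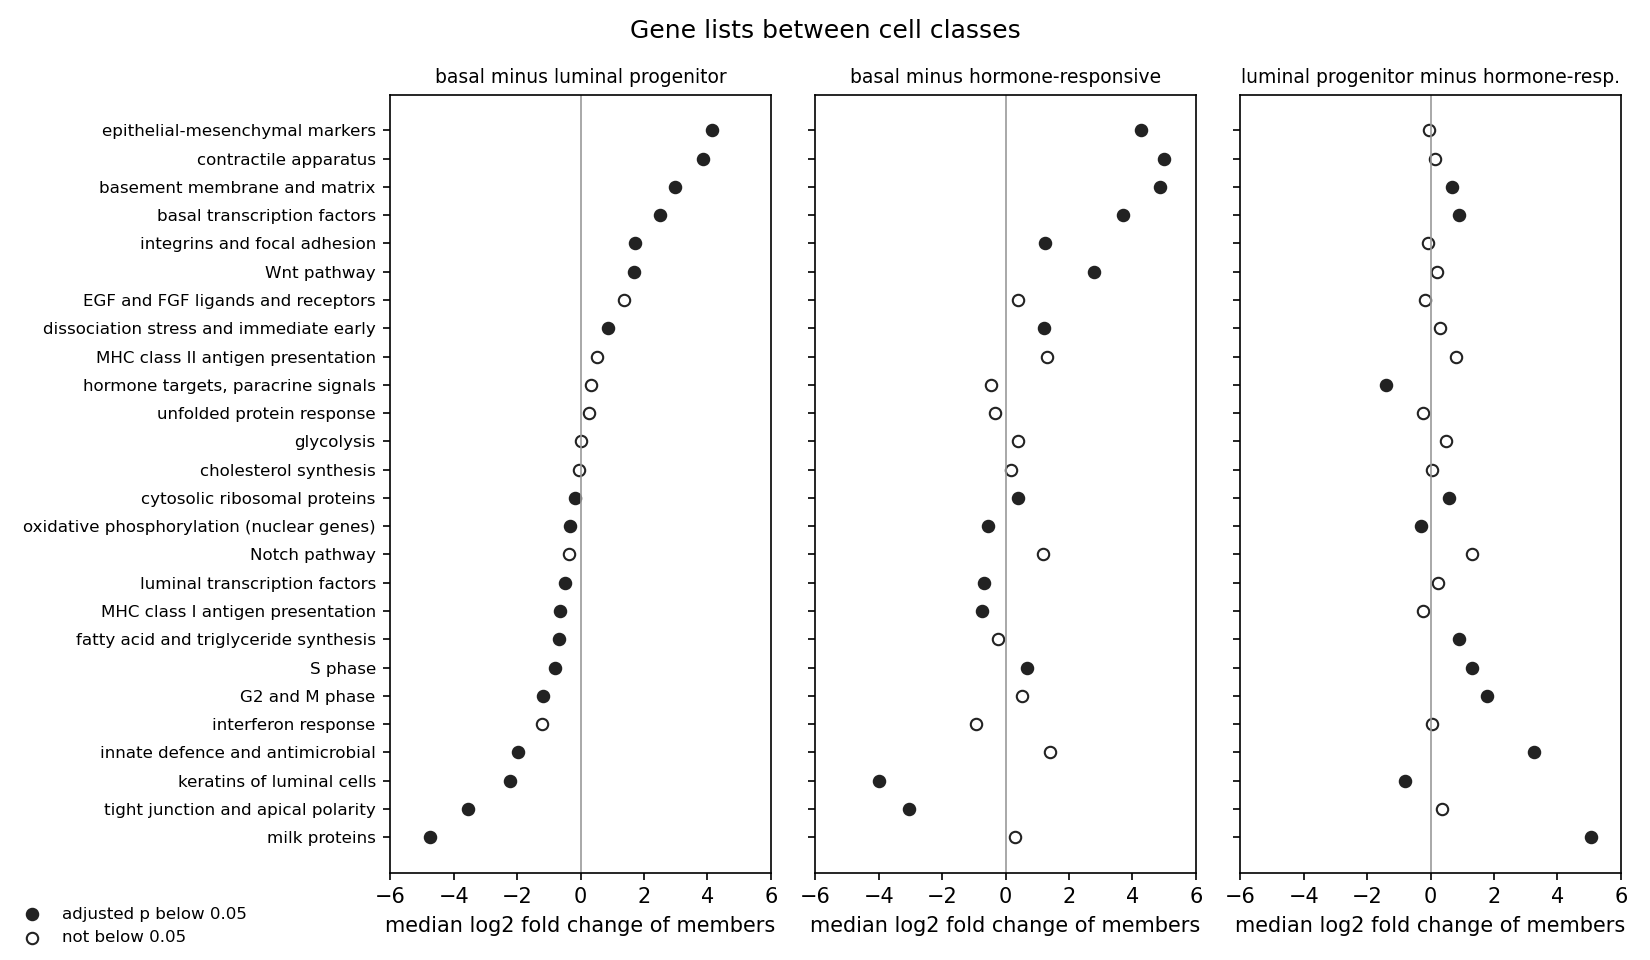
Median log2 fold change (horizontal axis) of the measured members of each of 26 gene lists in the 3 comparisons; filled points have an adjusted p below 0.05 by camera with its preset correlation, and none has with an estimated one. Contractile (3.85 and 4.99), matrix (2.99 and 4.88) and epithelial-mesenchymal genes (4.15 and 4.27) lie farthest towards basal-like cells in both comparisons that hold them.

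Between basal-like and hormone-responsive-like cells, single genes such as Tagln and Palld were higher in basal-like cells, and a neurexin and an arginase were higher in hormone-responsive-like cells. Tagln reached 1909 ± 672 CPM in basal-like and 13.8 ± 1.82 CPM in hormone-responsive-like cells, a log2 fold change of 7.05 ± 0.40 (adjusted p = 2e-07). Palladin (Palld; chromosome 8, 61511433 to 61902690, minus strand), which organises actin, reached 282 ± 41.9 and 2.32 ± 1.04 CPM, a log2 fold change of 6.70 ± 0.71 (adjusted p = 2e-07). The neurexin Nrxn3 (chromosome 12, 88722876 to 90334935, plus strand) reached 0.981 ± 0.379 CPM in basal-like and 160 ± 26.4 CPM in hormone-responsive-like cells, a log2 fold change of -7.40 ± 0.22 (adjusted p = 2.6e-07). Arginase Arg1 (chromosome 10, 24915221 to 24927484, minus strand) reached 1.42 ± 0.520 and 201 ± 42.2 CPM, a log2 fold change of -7.10 ± 0.37 (adjusted p = 2e-07).

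Of 12843 genes, 4596 were called, 2912 higher in basal-like and 1684 higher in hormone-responsive-like cells; 4542 kept 1 sign in all 3 libraries, and 7984 reached an unadjusted p below 0.05. The median log2 fold change over all genes tested was 0.13 in this comparison, relative to which small shifts of lists are read. Besides Tagln and Palld, the largest differences towards basal-like cells were in Sobp (7.50 ± 0.87), Tenm2 (7.23 ± 0.73), Speer4e (7.20 ± 0.82) and the calcium channel subunit Cacna2d1 (6.80 ± 0.86). Besides Nrxn3 and Arg1, those towards hormone-responsive-like cells were in the angiogenin ribonucleases Ang4 (-7.02 ± 0.64) and Ang5 (-6.66 ± 0.24), the mechanosensitive channel Piezo2 (-6.69 ± 0.62) and R3hdml (-6.49 ± 0.12). Ang4 and Ang5 are close paralogs, and the division of counts between them is uncertain.

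Of 22 contractile genes, 21 were higher in basal-like cells, 0 lower and 1 not called (21 and 0 adjusted over the list alone). Contractile genes had a median of 4.99 (adjusted p = 1.7e-11, and adjusted p = 0.076 with an estimated correlation). An example was filamin Flna (4.26 ± 0.21). Of 26 matrix genes, 22 were higher, 0 lower and 4 not called (23 and 0 adjusted over the list alone). Matrix genes had a median of 4.88 (adjusted p = 4.7e-10, and adjusted p = 0.105 with an estimated correlation). Examples were the type IV collagen chain Col4a1 (5.75 ± 0.46) and Hspg2 (4.79 ± 0.10). The list stood at a median log2 ratio of -0.55 in basal-like cells (4 of 25 over 2-fold lower, 1 higher) and -0.63 in hormone-responsive-like cells of library 1 (3 of 14 lower), and at 0.52 in hormone-responsive-like cells of library 2 (4 higher). Of 21 integrin and focal adhesion genes, 13 were higher, 0 lower and 8 not called (13 and 0 adjusted over the list alone). Adhesion genes had a median of 1.2 (adjusted p = 2.6e-05, and adjusted p = 0.076 with an estimated correlation). Examples were Itga9 (6.10 ± 0.35) and Itgb8 (4.67 ± 0.76). Of 15 epithelial-mesenchymal markers, 11 were higher, 0 lower and 4 not called (11 and 0 adjusted over the list alone). Mesenchymal markers had a median of 4.27 (adjusted p = 0.00076, and adjusted p = 0.193 with an estimated correlation). An example was Tgfb1i1 (5.63 ± 0.52). The 4 markers of at least 10 CPM in hormone-responsive-like cells had a median log2 ratio of 0.55 in library 2. Of 19 basal transcription factors, 17 were higher, 0 lower and 2 not called (17 and 0 adjusted over the list alone). Basal factors had a median of 3.71 (adjusted p = 1.1e-07, and adjusted p = 0.076 with an estimated correlation). Examples were Snai2 (6.68 ± 0.68) and Egr2 (4.80 ± 0.58). Of 29 Wnt genes, 21 were higher, 4 lower and 4 not called (21 and 4 adjusted over the list alone). Wnt genes had a median of 2.80 (adjusted p = 0.00012, and adjusted p = 0.076 with an estimated correlation). Wif1 (5.54 ± 0.55) and the R-spondin receptor Lgr4 (3.97 ± 0.66) were higher and Wnt7b (-4.76 ± 0.70) and the receptor Fzd6 (-1.32 ± 0.27) lower.

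Lower in basal-like than in hormone-responsive-like cells were 16 of 21 tight junction genes, with 1 higher and 4 not called (16 and 1 adjusted over the list alone). Junction genes had a median of -3.03 (adjusted p = 4.7e-08, and adjusted p = 0.177 with an estimated correlation). Cldn7 (-4.18 ± 0.07) was lower; the member that was higher, Cldn1 (2.33 ± 0.58), lay at 0.92 without doublet removal. Of 5 keratins of luminal cells, 4 were lower and 1 higher (4 and 1 adjusted over the list alone). Luminal keratins had a median of -4.00 (adjusted p = 0.01, and adjusted p = 0.436 with an estimated correlation). Krt7 (-5.59 ± 0.16) was lower and Krt23 (5.36 ± 1.20) higher. Of 23 luminal transcription factors, 8 were lower, 5 higher and 10 not called (8 and 5 adjusted over the list alone). Luminal factors had a median of -0.69 (adjusted p = 0.033, and adjusted p = 0.417 with an estimated correlation). Foxa1, which opens chromatin for the oestrogen receptor (-6.35 ± 0.22), and Spdef (-5.26 ± 0.04) were lower, and Tfap2c (3.69 ± 0.16) and Cebpb (3.51 ± 0.54) higher; without library 2 this list missed the threshold (adjusted p = 0.0572; range over 9 alternatives 0.008 to 0.417). Of 13 MHC class I genes, 4 were lower, 0 higher and 9 not called (4 and 0 adjusted over the list alone). Class I genes had a median of -0.74 (adjusted p = 0.0039, and adjusted p = 0.555 with an estimated correlation). Examples were Tap2 (-2.41 ± 0.42) and Psmb8 (-2.61 ± 0.43). Class I genes stood at a median log2 ratio of -0.44, 0.21 and 0.23 in basal-like cells of libraries 1, 2 and 3. In hormone-responsive-like cells they stood at 0.03, -0.24 and 0.21. Of 32 oxidative phosphorylation genes, 2 were lower (Atp5j at -1.09 ± 0.09 and Cox5a at -1.22 ± 0.17), 0 higher and 30 not called (2 and 0 adjusted over the list alone; median -0.56, adjusted p = 1.5e-07, and adjusted p = 0.396 with an estimated correlation).

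Of 25 dissociation stress genes, 16 were higher in basal-like cells, 1 lower and 8 not called (16 and 1 adjusted over the list alone). Stress genes had a median of 1.20 (adjusted p = 0.011, and adjusted p = 0.744 with an estimated correlation). Myc (3.36 ± 0.31) and the chaperone Hspa8 (1.37 ± 0.48) were higher and Klf2 (-2.44 ± 1.18) lower. Without library 1 the median of this list was 0.62 (adjusted p = 0.102) and Hspa8 lay at 0.97; without the replicate block adjusted p was 0.0604 (range over 9 alternatives 0.000705 to 0.744). In hormone-responsive-like cells of libraries 1, 2 and 3 the whole list had a median log2 ratio of -2.00, 0.84 and 1.11 (17 of 24 genes over 2-fold lower and 1 higher in library 1), against 0.16, -0.20 and 0.18 in basal-like cells. Its 6 heat-shock genes summed to 4692, 3613 and 3276 CPM in hormone-responsive-like cells of libraries 1, 2 and 3, against 19397, 4866 and 4620 CPM in basal-like cells. Of 30 S-phase genes, 8 were higher in basal-like cells, 0 lower and 22 not called (8 and 0 adjusted over the list alone). S-phase genes had a median of 0.68 (adjusted p = 0.042, and adjusted p = 0.631 with an estimated correlation). Examples were the replication clamp Pcna (1.66 ± 0.20) and the histone chaperone Nasp (2.19 ± 0.26). This call was lost without library 1 (adjusted p = 0.0607), without library 2 (adjusted p = 0.139) and without the replicate block (adjusted p = 0.0812), over a range of 0.0163 to 0.631 in 9 alternatives. Of 40 ribosomal protein genes, 1 was higher, Rpl7 at 1.07 ± 0.26, and 39 were not called (1 and 0 adjusted over the list alone). Ribosomal genes had a median of 0.38 (adjusted p = 0.0057, and adjusted p = 0.744 with an estimated correlation). Rpl7 lay at 0.89 without library 2 and between 0.95 and 0.99 under 5 other settings, and the list was lost without library 2 (adjusted p = 0.0534) and without library 3 (adjusted p = 0.0972), over a range of 0.000102 to 0.744 in 9 alternatives.

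The other 12 lists did not pass by camera in this comparison, with adjusted p between 0.0948 and 0.955, and an adjusted p of 0.373 or more with an estimated correlation. By fry, adjusted p was 5.3e-05 for Notch, 0.0017 for hormone target, 0.0071 for glycolysis and 0.017 for milk protein genes. It was 0.0871 or more for the others, and below 0.05 for each list that camera passed here. Members higher and lower in basal-like cells numbered 9 and 12 of 24 hormone targets and paracrine signals, 8 and 1 of 16 Notch pathway genes, 7 and 5 of 18 EGF and FGF ligands and receptors, 7 and 3 of 21 innate defence genes, 6 and 0 of 34 genes of G2 and M phase, 5 and 2 of 18 glycolysis genes, 3 and 6 of 17 interferon response genes, 3 and 4 of 20 genes of fatty acid synthesis, 3 and 4 of 22 unfolded protein response genes, 2 and 3 of 20 cholesterol synthesis genes, 2 and 2 of 5 MHC class II genes and 2 and 0 of 13 milk protein genes. Adjusted over the list alone, each of these numbers was the same. Median, mean and test differed in sign for cholesterol synthesis (median 0.18, mean -0.04) and MHC class II (median 1.30, mean 0.72, test lower).

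The luminal classes differed from each other in single genes such as a casein and a lipogenic regulator on the progenitor side, and a secreted hormone and an enzyme of serotonin synthesis on the hormone-responsive side. Alpha-S1 casein Csn1s1 (chromosome 5, 87666208 to 87682578, plus strand) reached 3674 ± 3010 CPM in luminal progenitor-like and 85.2 ± 71.9 CPM in hormone-responsive-like cells, a log2 fold change of 5.46 ± 0.14 (adjusted p = 1.8e-07). Thrsp (chromosome 7, 97412938 to 97417730, minus strand) reached 71.0 ± 57.1 and 1.08 ± 0.955 CPM, a log2 fold change of 5.97 ± 0.65 (adjusted p = 8.6e-07). Stc2, a secreted glycoprotein hormone (chromosome 11, 31357307 to 31370074, minus strand), reached 19.3 ± 2.73 CPM in luminal progenitor-like and 1535 ± 521 CPM in hormone-responsive-like cells, a log2 fold change of -6.27 ± 0.51 (adjusted p = 2.7e-07). Tph1, which starts serotonin synthesis (chromosome 7, 46644641 to 46672537, minus strand), reached 2.21 ± 0.358 and 148 ± 24.0 CPM, a log2 fold change of -6.05 ± 0.27 (adjusted p = 2.7e-07).

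Of 12843 genes, 3163 were called, 1871 higher in luminal progenitor-like and 1292 higher in hormone-responsive-like cells; 3094 kept 1 sign in all 3 libraries, and 6570 reached an unadjusted p below 0.05. Besides Thrsp and Csn1s1, the largest differences towards luminal progenitor-like cells were in Csn1s2a (5.65 ± 0.56), Csn2 (5.64 ± 0.56), Btn1a1 (5.50 ± 0.21) and the calcium sensor Ncald (5.42 ± 1.55). Those towards hormone-responsive-like cells were in Nrxn3 (-7.58 ± 0.73), uroplakin Upk3a (-7.03 ± 0.83), Itih2 (-6.88 ± 0.87), Fam25c (-6.86 ± 0.61), the collagen Col8a1 (-6.83 ± 0.50) and Sprr1a (-6.65 ± 1.14).

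Of 13 milk protein genes, 12 were higher in luminal progenitor-like cells, 0 lower and 1 not called (13 and 0 adjusted over the list alone). Milk genes had a median of 5.06 (adjusted p = 1.6e-10, and adjusted p = 0.076 with an estimated correlation). Milk genes had a median log2 ratio of -1.26, 0.60 and 0.55 in luminal progenitor-like and -0.84, 0.43 and 0.53 in hormone-responsive-like cells of libraries 1, 2 and 3 (6 of 12 and 4 of 8 over 2-fold lower in library 1). Among caseins, Csn1s1 stood at 216, 5842 and 4799 CPM in luminal progenitor-like and at 4.47, 155 and 121 CPM in hormone-responsive-like cells of libraries 1, 2 and 3. Of 21 innate defence genes, 17 were higher, 2 lower and 2 not called (17 and 2 adjusted over the list alone). Defence genes had a median of 3.26 (adjusted p = 0.00011, and adjusted p = 0.373 with an estimated correlation). In luminal progenitor-like cells this list stood apart by library, with a median log2 ratio to the other libraries of -1.22 in library 1 (9 of 16 genes over 2-fold lower) and 0.71 in library 3 (7 over 2-fold higher); in hormone-responsive-like cells it was -0.77 in library 1 (4 of 9 lower) and 0.60 in library 2 (1 higher). Muc15 (5.41 ± 0.15) and complement C3 (4.53 ± 0.22) were higher, and the chemokine Cxcl15 (-6.39 ± 0.38) and Slpi (-3.13 ± 1.51) lower, the latter with an adjusted p of 0.0598 without library 3 (range over 18 alternatives 5.72e-05 to 0.0598). Of 20 genes of fatty acid and triglyceride synthesis, 9 were higher, 2 lower and 9 not called (9 and 2 adjusted over the list alone). Lipid genes had a median of 0.90 (adjusted p = 0.023, and adjusted p = 0.436 with an estimated correlation). Without the replicate block adjusted p was 0.052 (range over 9 alternatives 0.00561 to 0.436). By library, the median log2 ratio of this list was -0.44, 0.36 and 0.12 in luminal progenitor-like cells (4 of 17 over 2-fold lower in library 1). In hormone-responsive-like cells it was -0.27, 0.15 and 0.14 (2 of 15 lower in library 1). The fatty-acid binding protein Fabp5 (4.06 ± 0.65) was higher and Dgat2 (-4.47 ± 0.33) lower; Scd2 (-1.70 ± 0.72) was lower, with an adjusted p of 0.0856 without the replicate block (range over 18 alternatives 1.11e-09 to 0.0856).

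Of 30 S-phase genes, 20 were higher in luminal progenitor-like cells, 0 lower and 10 not called (20 and 0 adjusted over the list alone). S-phase genes had a median of 1.30 (adjusted p = 1.5e-07, and adjusted p = 0.317 with an estimated correlation). Examples were Mcm5 (2.13 ± 0.42) and the DNA polymerase Pola1 (2.41 ± 0.23). Across libraries 1, 2 and 3 the median log2 ratio of S-phase genes was -0.02, 0.62 and -0.56 in luminal progenitor-like cells (4 of 24 over 2-fold higher in library 2, 2 lower in library 3), against -0.05, -0.03 and -0.21 in hormone-responsive-like cells. Of 34 genes of G2 and M phase, 23 were higher, 0 lower and 11 not called (25 and 0 adjusted over the list alone). G2 and M genes had a median of 1.78 (adjusted p = 1.45e-05, and adjusted p = 0.436 with an estimated correlation). Examples were Cdk1 (3.03 ± 0.19) and the topoisomerase Top2a (2.77 ± 1.95). This list stood in luminal progenitor-like cells of library 1 at a median log2 ratio of -1.12 (9 of 16 over 2-fold lower). Of 19 basal transcription factors, 9 were higher, 0 lower and 10 not called (9 and 0 adjusted over the list alone). Basal factors had a median of 0.90 (adjusted p = 0.0031, and adjusted p = 0.121 with an estimated correlation). Examples were Tcf7l2 (3.05 ± 0.09) and Sox10 (4.20 ± 0.42). Of 26 matrix genes, 12 were higher, 3 lower and 11 not called (12 and 3 adjusted over the list alone). Matrix genes had a median of 0.68 (adjusted p = 0.046, and adjusted p = 0.522 with an estimated correlation; adjusted p = 0.119 without the replicate block, range over 9 alternatives 0.0244 to 0.522). Col16a1 (2.1 ± 0.33) was higher, and the laminin chain Lama5 (-2.32 ± 0.13) lower. Matrix genes in hormone-responsive-like cells had a median log2 ratio of -0.63 in library 1 (3 of 14 over 2-fold lower) and 0.52 in library 2 (4 higher). In luminal progenitor-like cells it was -0.47 in library 1 (5 of 21 lower) and 0.44 in library 2 (4 higher). Of 40 ribosomal protein genes, 0 were called, also when adjusted over the list alone (median 0.58, adjusted p = 1.5e-07, and adjusted p = 0.549 with an estimated correlation).

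Of 24 hormone targets and paracrine signals, 13 were higher in hormone-responsive-like cells, 4 lower and 7 not called (13 and 4 adjusted over the list alone). Hormone targets had a median of -1.41 (adjusted p = 0.0036, and adjusted p = 0.317 with an estimated correlation). Besides Tph1 and Stc2, the glucocorticoid receptor Nr3c1 (3.04 ± 0.27) and the binding protein Igfbp5 (4.63 ± 0.94) were called, both higher in luminal progenitor-like cells. Of 5 keratins of luminal cells, 2 were higher in hormone-responsive-like cells, 1 lower and 2 not called (2 and 1 adjusted over the list alone). Luminal keratins had a median of -0.81 (adjusted p = 0.043, and adjusted p = 0.544 with an estimated correlation). Krt7 (-3.35 ± 0.24) and Krt19 (-1.74 ± 1.10) were higher there, and Krt23 (2.74 ± 0.80) lower. These keratins stood at a median log2 ratio of -1.11, 0.19 and 0.74 in luminal progenitor-like cells of libraries 1, 2 and 3 (3 of 5 over 2-fold lower in library 1), against -0.04, -0.09 and 0.05 in hormone-responsive-like cells. With median-of-ratios factors and without doublet removal, this list missed the threshold (adjusted p = 0.0504 in both; range over 9 alternatives 0.0153 to 0.544). Of 32 oxidative phosphorylation genes, 0 were called, also when adjusted over the list alone (median -0.31, adjusted p = 5.5e-05, and adjusted p = 0.46 with an estimated correlation).

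The other 15 lists did not pass by camera in this comparison, with adjusted p between 0.0565 and 0.935, and an adjusted p of 0.323 or more with an estimated correlation. By fry, adjusted p was 0.00023 for Notch, 0.00059 for Wnt, 0.0059 for glycolysis and 0.0071 for integrin genes. It was 0.01 for luminal factors, 0.021 for tight junctions, 0.022 for EGF and FGF and 0.043 for contractile genes. For the others it was 0.131 or more, and for each list that camera passed here below 0.05. Members higher in luminal progenitor-like and in hormone-responsive-like cells numbered 12 and 5 of 29 Wnt genes, 9 and 2 of 16 Notch pathway genes, 6 and 1 of 18 glycolysis genes, 5 and 5 of 23 luminal transcription factors, 5 and 2 of 25 dissociation stress genes, 4 and 5 of 21 integrin and focal adhesion genes, 4 and 4 of 17 interferon response genes, 4 and 0 of 21 tight junction genes, 3 and 0 of 22 contractile genes, 2 and 4 of 18 EGF and FGF ligands and receptors, 2 and 3 of 15 epithelial-mesenchymal markers, 2 and 2 of 20 cholesterol synthesis genes, 1 and 5 of 22 unfolded protein response genes, 1 and 1 of 5 MHC class II genes and 0 and 2 of 13 MHC class I genes. Adjusted over the list alone, the numbers changed to 4 and 2 for dissociation stress, 1 and 1 for cholesterol synthesis and 2 and 1 for MHC class II, and were the same for the others. Median, mean and test differed in sign for luminal transcription factors (median 0.25, mean -0.003, test higher), cholesterol synthesis (median 0.04, mean -0.02, test lower), interferon response (median 0.04, mean 0.30, test lower) and MHC class II (median 0.79, mean 0.33, test lower).

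Library 1 stood apart from libraries 2 and 3 within each class. Among genes with a mean of at least 10 CPM, 166 were over 2-fold higher and 139 over 2-fold lower in library 1 than in the mean of the other two in basal-like cells, 175 and 261 in luminal progenitor-like cells and 134 and 239 in hormone-responsive-like cells. For library 2 these numbers were 34 and 42, 53 and 57, and 56 and 23, and for library 3 they were 18 and 31, 128 and 28, and 63 and 38. The inducible heat-shock gene Hspa1a stood at 4645, 425 and 368 CPM in basal-like cells and at 1900, 317 and 302 CPM in luminal progenitor-like cells of libraries 1, 2 and 3. The neighbouring copy Hspa1b is near-identical, so counts of each are uncertain. Csn2 stood at 156, 8159 and 4863 CPM and the naming marker Wfdc18 at 1733, 7662 and 5377 CPM in luminal progenitor-like cells, whereas Csn3 stood at 5316, 2926 and 4472 CPM. Each library is 1 sample, so these differences have no replicate check and no p-value.

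**Figure D4:**
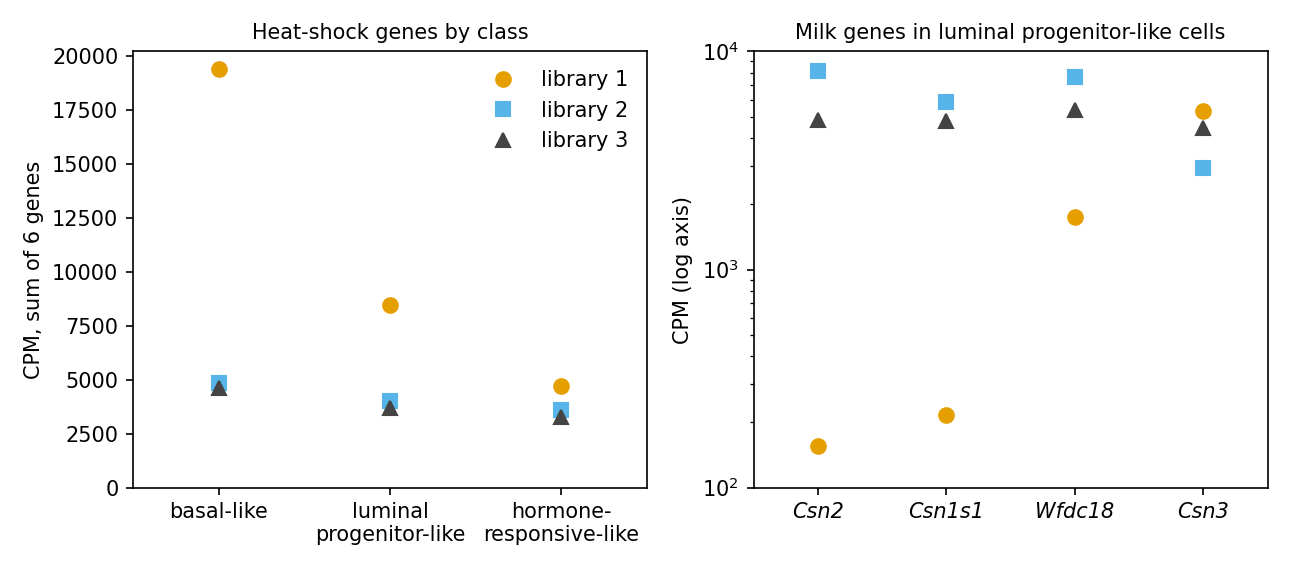
Left, summed CPM of 6 heat-shock genes (vertical axis, from 0) in each class. Right, under the heading of milk genes, CPM (log axis) of the caseins Csn2, Csn1s1 and Csn3 and of the naming marker Wfdc18 in luminal progenitor-like cells. Points are the 3 libraries. Library 1 lies highest for the summed heat-shock genes in each class (19397 CPM in basal-like cells) and lowest for Csn2, Csn1s1 and Wfdc18, while its Csn3 level is the highest of the 3.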

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

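The tests of other splits of the sums, of free RNA from basal cells, of doublets and of red blood cells were chosen only after the results were seen.

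Cells of clusters that carried both basal and luminal markers, formed without doublet removal, were not compared as a class of their own. They were counted because they lay above the limit that a count of 0 allows. They made up 0.205%, 3.22% and 5.36% of cells before doublet removal in libraries 1, 2 and 3 (13 of 6343, 288 of 8934 and 592 of 11043 cells); the doublet filter removed 92.3%, 88.9% and 92.9% of them, and the rest were kept. If they were doublets, their depth would be near the sum of 2 cells, and the lowest ratio to that sum in libraries with at least 20 such cells was 1.04, as doublets need. Their median Scrublet scores of 0.323, 0.436 and 0.424, above the 90th percentile of other cells (0.129, 0.126 and 0.141), go with doublets too, but a cell state with both programmes would also score high. The ratio of observed cells to expected doublets was 0.0912, 1.00 and 1.42 in libraries 1, 2 and 3. Doublets that clustered with a single class were not counted, so the low value of library 1 does not weigh against doublets. For the same reason this ratio cannot decide whether doublets are the whole account, which stays open. A cell state with both programmes also stays open, since its highest ratio, 1.42, lay between the bounds set for and against it.

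UMIs of the alpha-globin gene Hba-a1 in hormone-responsive-like cells belonged to no comparison and lay above the limit that a count of 0 allows. They were present in 21%, 20.8% and 20.2% of these cells in libraries 1, 2 and 3, against a mean of 0.605% ± 0.364 of basal-like and 0.949% ± 0.596 of luminal progenitor-like cells, at median depths of 3390, 1923 and 2930 UMIs. Red blood cell RNA would bring beta-globin, but beta-globin UMIs over alpha-globin UMIs came to 0.0148 in hormone-responsive-like cells, against 0.731 in basal-like and 0.724 in luminal progenitor-like cells, which argues against it. Depth is argued against as well, since after thinning to 1000 UMIs the share was at least 24.3 times the higher of the other classes in each library. Assignment of reads between Hba-a1 and the near-identical Hba-a2 was not tested, and no biological explanation was tested.

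Library 1 stood apart in the median of 6 heat-shock genes, higher in each class although Dnajb1 (-0.67) and Hspa8 (-0.03) were not in hormone-responsive-like cells, nor Hspa8 (-0.04) in luminal progenitor-like cells, and in Csn2, Csn1s1 and Csn1s2a, lower in luminal progenitor-like cells although Csn3 was not. Low-quality single cells are argued against: with at least 1000 genes and under 5% mitochondrial UMIs, the second-highest share of the heat-shock log2 ratio kept was 1.05, and the median log2 ratio of 3 caseins in luminal progenitor-like cells was -5.32. Free RNA from 1 class, tested on heat-shock genes, was first left undecided by a lowest class level of 0.242 of the highest; a second test, for basal cells, found an excess in luminal classes at least 9.18 times what Acta2 would allow, which argues against that source. The absence of 1 casein-rich cluster is argued against as the whole cause, because in libraries 2 and 3 the share of luminal progenitor-like cells with a casein UMI exceeded the basal share and that cluster together by at least 23.7 points. A difference in RNA quality across all cells stays open, as Malat1 (log2 ratio 0.75, 1.36 and 0.91) and the median mitochondrial share (2.88%, 2.49% and 4.40%) were higher in basal-like, luminal progenitor-like and hormone-responsive-like cells of library 1 than in the other libraries; so do handling of the tissue and differences between animals, which were not tested.

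The 6 sums of each pair of classes can be split in 10 ways, too few for a share under 0.05. The real split called 4000, 4143 and 3011 genes in the 3 comparisons, the highest other split 0, and 1 split in each, the real one, called as many. Only 3 of the other splits part all 3 pairs of sums, as the real one does. Each other split puts sums of both classes in each group, so the class difference counts as spread within groups. Calls are then nearly precluded, and the 0 calls of those splits are no support for the real one.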

How the results depend on the processing

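The alternative with a separate TMM reference for each set of genes was added after seeing the data, and called 4016, 4600 and 3141 genes in the 3 comparisons, against 4021, 4596 and 3163. All 54 alternative totals of genes called stayed within 1.5 times, but counts by direction could move more. With sums thinned to equal totals, genes higher in basal-like than in luminal progenitor-like cells fell from 2417 to 1559. Against hormone-responsive-like cells, 2912 higher and 1684 lower became 2678 and 1918 with classes from all variable genes. With separate references they became 2796 and 1804. Leaving out 1 library gave 3454 to 4321, 4056 to 4816 and 2371 to 3533 genes, and the other settings 2755 to 4692, 3439 to 5058 and 2251 to 3544, each lowest when sums were thinned to equal totals. With no replicate block, 3798, 4390 and 2918 genes were called. Similar totals need not hold the same genes. Of the 4021, 4596 and 3163 genes called in the main setting, 2477, 3114 and 2039 were also called with thinned sums. In that setting 10279 genes were tested.

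Gene lists depended on the setting for the correlation. With a correlation estimated from the data, 0, 0 and 0 lists passed, against 18, 14 and 11 with the preset one. Estimates lay above the preset 0.01 for most lists that passed. They reached 0.719 for ribosomal, 0.677 for dissociation stress, 0.583 for MHC class I and 0.55 for luminal keratin genes. Preset p-values of such lists may be too small. The size of the correlation is not the whole account. Estimates for the integrin (-0.009), Wnt (-0.015) and basal factor lists (-0.008) lay below the preset 0.01, yet these lists lost their calls too. For the integrin list of the first comparison, the unadjusted p by camera rose from 1e-07 to 0.0043. What else changed with the setting was not tested. The adjusted p of 0.076 was 1 value tied over several lists, so it does not rank them. Of 387 single list results under alternatives, 327 kept their call and 60 lost it, 43 of them under the estimated correlation.

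Of 2355 results for single genes under alternatives, 2343 kept their call, 12 lost it and 0 reversed. These genes were picked for large changes or small p in the same data, so they say little about the other called genes. Ccl20 and Nusap1 gave no value with thinned sums, nor did Ccl20 without library 2. Of 42 shares, 41 moved by less than 1 SD. Leaving out 1 of 3 libraries cannot move a mean by 1 SD of the 3, so those rows could not fail. The SD was also wide: luminal progenitor-like cells made up a mean of 46.1% ± 15.9, and 37.5% without library 1. The share of hormone-responsive-like cells with a Top2a or Mki67 UMI was 2.76% without thinning, against 1.55% with it. Thinning removes UMIs from deeper cells and leaves out shallower ones, and these effects were not tested apart.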

Other observations

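Each library is 1 sample, so the values below have no replicate check, and the genes and lists were chosen after their values were seen. In basal-like cells of library 1, cholesterol synthesis genes stood higher than in the other libraries (median log2 ratio 1.77 over 13 genes, 8 of them over 2-fold higher). In luminal progenitor-like cells of library 3, interferon response genes stood higher (median log2 ratio 1.71 over 12 genes), as did MHC class I genes (0.86 over 12 genes). The dissociation stress and immediate-early list stood lower in library 1 in hormone-responsive-like cells (-2.00 over 24 genes) and in luminal progenitor-like cells (-1.14 over 25 genes), although the median of its 6 heat-shock genes stood higher (0.46 and 1.64).

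Among single genes, Txnip stood at 2403, 582 and 613 CPM and the nuclear RNA Malat1 at 30005, 11368 and 12096 CPM in luminal progenitor-like cells of libraries 1, 2 and 3. Fos stood at 933, 4826 and 4893 CPM in hormone-responsive-like cells. The metallothionein Mt1 stood at 8573, 4532 and 5759 CPM in basal-like cells and at 490, 1811 and 2950 CPM in luminal progenitor-like cells, so library 1 was the highest in one class and the lowest in the other.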
